A study of Mus musculus and Homo sapiens with 14 samples.

How the data were processed

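Poly(A) RNA of mouse brain and cecum and of HCT116 cells was fragmented, treated with bisulfite, which converts unmethylated cytosines, and made into strand-specific libraries, per the labels' protocols. The authors deposited 1 list per library, with a chromosome, a position and a value, and no header. Each deposited value is a methylation fraction between 0.1 and 1 with 3 decimals. The deposited lists give no read number, strand or p-value, so no coverage minimum could be set, the precision of single levels is unknown, and no counts were inferred from the fractions. The submitters' processing notes name cutadapt 1.18 and FastQC 0.11.9 and the builds mm39 and hg38, and the names of the deposited lists contain meRanTK. The aligner, the caller's settings, the bisulfite conversion rate and the authors' coverage and significance filters are not given in the sources used here. Because only cytosines at 0.1 or more are listed, mean levels over listed sites are bounded from below, and differences near the limit are compressed.

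Mouse libraries were grouped from the labels as brain GF, brain SPF, cecum GF and cecum SPF with 3 libraries each, and the HCT116 libraries as empty plasmid and NSUN2 with 1 each. The label of the SPF samples gives their treatment as water. The plan fixed before the data were examined was a quasi-binomial model of methylated and unmethylated reads, with limma on transformed levels in its place if reads were not given. The second was therefore used, on log2((level + 0.01) / (1 - level + 0.01)), for sites listed in at least 2 libraries of each group (GF against SPF, and the interaction) or at least 4 libraries of each tissue (brain against cecum, with the state as a covariate). Unlisted values were left missing. The Benjamini-Hochberg threshold was 0.05. Numbers of listed sites and mean levels over sites listed in all libraries compared were tested with exact two-sided permutation tests, 6 in all with Benjamini-Hochberg adjustment over them. Sites listed in one group alone were counted and compared with other splits of the libraries. HCT116 counts have exact 95% intervals, which cover counting error only.

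The sites named were set by a rule fixed before the data were examined. It takes up to 10 sites in each direction past the threshold, or the 10 with the smallest p where fewer pass, up to 5 for the interaction, the 10 largest HCT116 differences each way, and the 10 highest levels per tissue among sites listed in all its libraries. The rule asked in HCT116 for sites past a test, which could not be run, so the largest differences are given without one. Sites listed in one group or tissue alone and clusters of neighbouring sites were chosen after their values were seen. The rule also named genes, and the only annotation at hand was a gene table of another mouse build, so no gene names, transcript regions, sequence contexts or gene lists were analysed here.

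The site test was tried on simulated levels with the measured means and listing patterns and with the median spread of the sites given to every site, in 20 runs per comparison. The lower limit of the lists was not simulated, so the shares may not hold for sites with more spread or near the limit. An equal spread also favours a test that pools the spread over sites. The recovered shares may therefore be too high even for sites of median spread. With 20% of sites changed, false calls made up 4.67% of the calls for brain, 2.51% for cecum and 4.40% for brain against cecum, where a change of 1 on the log2 odds scale was recovered at 90% of the sites given it. Alternatives left out each library in turn, used the replicate number as a block, removed sites with 2 or more other sites within 10 nt (without regard to strand), removed mitochondrial and unplaced sequences, kept sites at 0.2 or more, and changed how many libraries had to list a site. Alternatives chosen after the data were examined were an offset of 0.001, untransformed levels, 10 kb regions, site sharing, sites listed in one tissue alone, medians in place of means over shared sites, and the test with states shuffled within tissue. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.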

Results

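RNA 5-methylcytosine (m5C), a methyl mark on cytosines of messenger and other RNA, was measured by bisulfite sequencing of poly(A) RNA in 12 mouse libraries and 2 human libraries. The mouse libraries came from the brain and the cecum of germ-free mice (GF, raised without microbes) and of specific-pathogen-free mice (SPF, which carry a gut microbiota) at 8 weeks of age, with 3 libraries in each of the 4 groups. The human libraries came from HCT116, a colorectal cancer cell line, 48 h after transfection with an empty pcDNA3 plasmid or with a plasmid for NSUN2, an m5C methyltransferase of RNA, with 1 library each. Each library was a list of cytosines with a methylation level of at least 0.1, given as a fraction. The number of reads behind each level was not given, so the depth is unknown, and an unlisted cytosine can have been less methylated or too thinly covered. Positions are those of mm39 for mouse and hg38 for human, and no gene or transcript annotation of these builds was used here.

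Mouse libraries listed 2397 to 8906 sites, with a mean of 5682 ± 1850 (SD, n = 12). Most listed levels were low. The median level of a library lay between 0.122 and 0.125, 79.5% to 82.2% of the sites of a library were below 0.15, and 3.28% to 4.82% were at 0.2 or more. Of 63653 mouse positions, 95.8% were listed in 1 library only and 9 were listed in all 12. Whether at least 1 other library of the same tissue listed a site went with its level. The share was 8.42% ± 1.12 (SD, n = 12) for sites between 0.1 and 0.15, 37.3% ± 8.51 between 0.2 and 0.3, and 93.9% ± 8.66 at 0.4 or more. In HCT116, the shares of the sites at 0.4 or more that were listed in both libraries were 55.3% and 61.4%. Only 1 other library could list a site there, against several in mouse, so the shares of mouse and HCT116 are not alike.

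**Figure D1:**
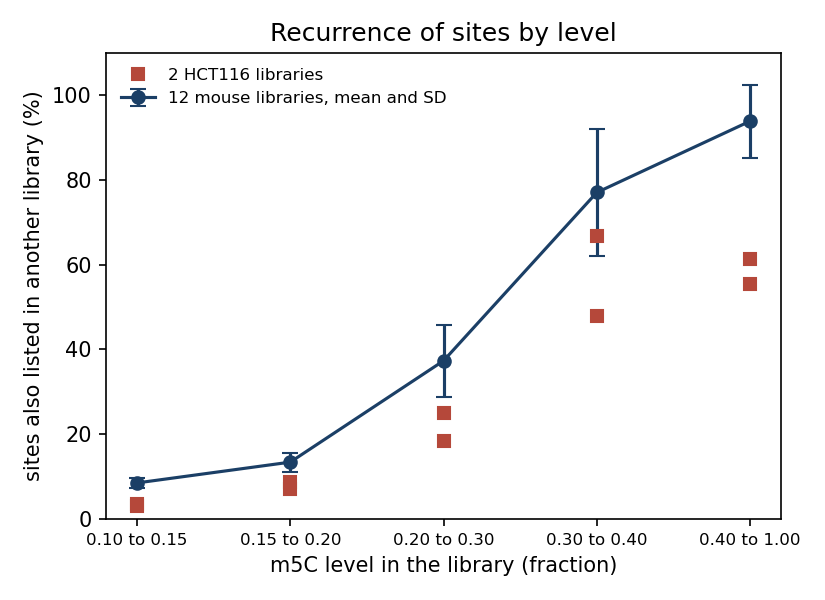
Percent of a library's m5C sites that at least 1 other library of the same tissue (mouse) or the other library (HCT116) also listed, by the level of the site as a fraction. Circles and bars give the mean and SD of the 12 mouse libraries, which rose from 8.42% to 93.9%, and each square is 1 of the 2 HCT116 libraries.

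The highest levels were found at a few recurrent positions. On chromosome 9, position 123291082 stood at 0.977 ± 0.00147 in brain and 0.972 ± 0.00543 in cecum (SD, n = 6 each) and was listed in every mouse library. Position 78397929 of chromosome 12 stood at 0.972 ± 0.0134 in cecum (n = 6) and at 0.973 ± 0.0262 in the 4 brain libraries that listed it. The next highest brain sites listed in all 6 brain libraries were chromosome 12 position 109533929 at 0.624 ± 0.0476, chromosome 4 position 41518020 at 0.533 ± 0.0643, chromosome 19 position 46301265 at 0.512 ± 0.0480 and chromosome 11 position 115969783 at 0.469 ± 0.0631. In cecum they were chromosome 8 position 27630368 at 0.383 ± 0.0654, chromosome 8 position 85397525 at 0.369 ± 0.0546 and chromosome 5 position 135041263 at 0.357 ± 0.0926 (SD, n = 6 for each value).

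The comparison of GF with SPF mice asked whether the gut microbiota goes with a different m5C landscape in the brain. Across the 58 sites listed in all 6 brain libraries, the mean level was 0.242 ± 0.0256 in GF and 0.270 ± 0.00793 in SPF (SD, n = 3 each), and each GF library lay below each SPF library in this mean. The library medians over the same sites overlapped, at 0.1805, 0.2285 and 0.217 in GF and 0.226, 0.2275 and 0.2015 in SPF, with a difference of -0.00967 (exact permutation p = 0.7), while the median of the differences at single sites was -0.0268. The mean was lower in GF at 45 of these sites and higher at 13. At 8 of the 58 sites all GF libraries were below all SPF libraries and at 1 site all were above, together 15.5% of the sites where chance gives 10%. The sites share the same libraries and are not independent, so this share was not tested and adds no separate support. The difference of -0.0277 had an exact permutation p of 0.1 (two-sided), the smallest that 3 libraries against 3 can give, and an adjusted p of 0.3 over the 6 such comparisons made here. Without brain GF replicate 1, which had the lowest mean at 0.213, the difference was -0.0111 over 70 sites (exact permutation p = 0.3). Over all sites that each library listed, most of them near the limit of 0.1, the brain difference was -0.00136 (exact permutation p = 0.1), far smaller than over the shared sites.

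No single brain site passed the test as planned, and the closing section gives alternatives in which 1 or 2 did. Of 197 sites listed in at least 2 libraries of each group, 0 had an adjusted p under 0.05 in limma with Benjamini-Hochberg adjustment, and 12 had an unadjusted p under 0.05. Of the 10 sites with the smallest p, none of which passed, 9 had the lower mean in GF. Position 69670443 of chromosome 11 stood at 0.301 ± 0.0101 in GF (n = 3) and 0.541 ± 0.144 in SPF (n = 2), with a limma adjusted p of 0.358. Position 152387987 of chromosome 4 stood at 0.188 ± 0.0547 in GF and 0.482 ± 0.223 in SPF (n = 3 each). Without SPF replicate 1, at 0.228, it passed (limma adjusted p = 0.000225). Position 61365382 of chromosome 8 stood at 0.145 ± 0.0163 and 0.310 ± 0.0516 (n = 2 each). Position 68361969 of chromosome 14 stood at 0.147 in GF and 0.272 in SPF, and position 99571767 of chromosome 13 at 0.117 and 0.207. Position 126722192 of chromosome 8 had the opposite order, at 0.196 in GF and 0.118 in SPF. In simulated data of the same size, a change of 1 on the log2 odds scale was recovered at 58.5% of the sites given it and a change of 2 at 99.7%. There every site had the same median spread and no lower limit. The test pools the spread over sites, so these shares may be too high even for sites of median spread. They do not cover sites with more spread. The estimate at position 152387987 of chromosome 4, for example, was -1.94 on this scale and did not pass.

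GF brain libraries listed 6389 ± 1246 sites and SPF brain libraries 5698 ± 3255 (SD, n = 3 each; exact permutation p = 0.8, two-sided). The direction rested on SPF replicate 3, with 2397 sites, since without it the difference of GF from SPF was -959. In brain, 7 sites were listed in all GF libraries and no SPF library and 8 sites in all SPF libraries and no GF library. Their mean levels lay near the lower limit of the lists, the highest being 0.154 ± 0.0835 (n = 3) at position 34848427 of chromosome 17 in SPF and 0.135 ± 0.0252 at position 126071334 of chromosome 7 in GF. Leaving out a library relaxes this rule, so the count can only stay or rise. Without 1 library each, the total of 15 rose to between 32 and 115, the latter without GF replicate 2 and without SPF replicate 3.

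In the cecum, which is in direct contact with gut microbes, the same comparison gave a mean level of 0.274 ± 0.00935 in GF and 0.299 ± 0.0122 in SPF over the 26 sites listed in all 6 libraries (SD, n = 3 each). Each GF library again lay below each SPF library in this mean, and the mean was lower in GF at 17 sites and higher at 9. The library medians overlapped here too, at 0.2145, 0.1995 and 0.231 in GF and 0.2215, 0.2755 and 0.2135 in SPF, with a difference of -0.0218 (exact permutation p = 0.5), and the median of the differences at single sites was -0.0122. At 6 of the 26 sites all GF libraries were below all SPF libraries and at 1 site all were above, together 26.9% where chance gives 10%. As in brain, the sites share their libraries, so this share was not tested and adds no separate support. The difference of -0.0253 had an exact permutation p of 0.1 (two-sided), again the smallest possible, and an adjusted p of 0.3. Over all sites that each library listed, the cecum difference was 3.81e-05 (exact permutation p = 0.9). Over the sites shared by the libraries left, it was -0.0122 without cecum GF replicate 1 (36 sites) and -0.0150 without cecum SPF replicate 2 (38 sites). The difference between GF and SPF did not differ detectably between the tissues, with a gap of -0.00240 between brain and cecum (permutation of the states within each tissue, 400 arrangements, p = 0.935).

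A test over both tissues, chosen after the data were examined, shuffled the GF and SPF states within each tissue and averaged the 2 differences. The mean difference was -0.0265, and its exact permutation p over 400 arrangements was 0.005, the smallest that this design can give. Because each GF library had already been seen to lie below each SPF library in both tissues, this p restates that separation and adds no separate evidence. The test did not pass with library medians over the same sites, at -0.0158 (permutation p = 0.285), or with means over all sites that each library listed, at -0.000663 (permutation p = 0.15). For the means over shared sites, the p was 0.05 without cecum GF replicate 1, where the difference was -0.0199, and 0.005 to 0.035 without any other single library. The labels do not say whether a brain and a cecum library came from the same mouse or which libraries came from separate mice, so these p-values measure the spread between these libraries.

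**Figure D2:**
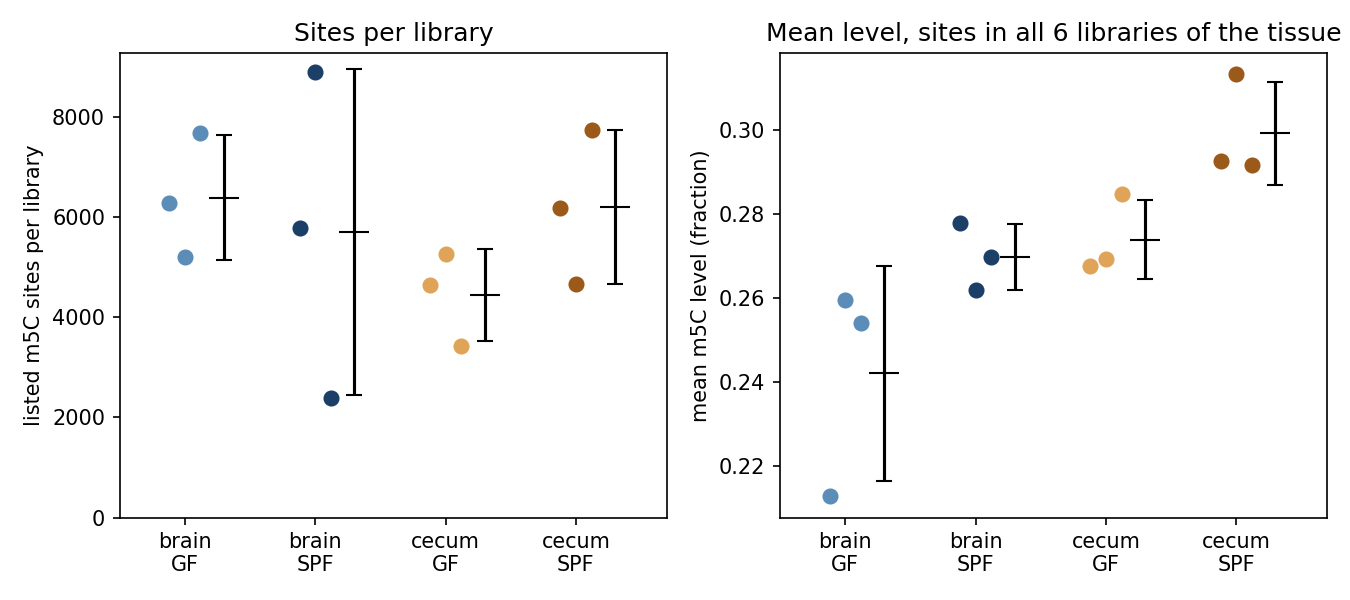
Left, listed m5C sites per library, and right, mean m5C level as a fraction over the sites listed in all 6 libraries of the tissue (58 in brain, 26 in cecum), by tissue and GF or SPF state. Each point is 1 library and the black bars give the mean and SD of 3 libraries. In both tissues each GF library lies below each SPF library in mean level, while site numbers overlap in brain and cecum. Library medians over the same sites, not drawn, also overlap in both tissues.

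At single sites, 0 of 85 tested cecum sites had an adjusted p under 0.05 (limma, Benjamini-Hochberg) and 10 had an unadjusted p under 0.05. Those 10 sites are the ones named by rule, and 7 of them had the lower mean in GF. The 85 tested sites as a whole showed no such direction. Of them, 43 were higher in GF, and the median difference was 0.0015 on the log2 odds scale. The smallest adjusted p, 0.135 in limma, belonged to position 37143356 of chromosome 9, at 0.211 ± 0.0294 in GF (n = 3) and 0.452 ± 0.0877 in SPF (n = 2). Position 4408254 of chromosome 16 stood at 0.149 ± 0.0605 in GF and 0.262 ± 0.0133 in SPF, position 52294115 of chromosome 10 at 0.167 ± 0.0318 and 0.260 ± 0.0319, and position 88480771 of chromosome 6 at 0.267 ± 0.0310 and 0.366 ± 0.0208 (SD, n = 3 each). Without cecum GF replicate 3, position 4408254 of chromosome 16 passed (limma adjusted p = 0.0243). Higher means in GF were seen at position 5697611 of chromosome 19, with 0.468 in GF and 0.267 in SPF, and at position 123193272 of chromosome 8, with 0.329 and 0.195. In simulated data of the same size, a change of 1 on the log2 odds scale was recovered at 62.8% of the sites given it and a change of 2 at 99.4%. As for brain, every simulated site had the same median spread and no lower limit. These shares may therefore be too high, and sites with more spread are not covered.

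Cecum libraries of GF mice listed 4445 ± 927 sites and those of SPF mice 6198 ± 1537 (SD, n = 3 each; exact permutation p = 0.2, two-sided). Without single libraries, the difference of GF from SPF ran from -2520 to -984. In cecum, 9 sites were listed in all GF libraries and no SPF library, and 19 in all SPF libraries and no GF library. One of the latter had a high level. Position 125163409 of chromosome 6 stood at 0.843 ± 0.0161 (SD, n = 3) in SPF cecum and was listed in no GF cecum library and in no brain library. Among the sites listed in GF cecum alone, the highest was position 102057688 of chromosome 15 at 0.313 ± 0.00839, followed by position 57011751 of chromosome 1 at 0.248 ± 0.0707 (SD, n = 3 each). Adjacent cytosines at positions 102171599 and 102171600 of chromosome 14 were listed in SPF cecum alone, at 0.241 ± 0.0718 and 0.144 ± 0.0110. Under the rule relaxed by leaving out 1 library each, the total of 28 rose to between 74 and 131, the latter without SPF replicate 2.

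Brain and cecum differed in which sites were listed. Libraries of the same tissue shared 3.45% of their sites on average, as shared sites over the geometric mean of the numbers listed, and libraries of different tissues shared 1.56%. The difference had a permutation p of 0.00216 over the 462 splits of the 12 libraries, the smallest possible. At a level of 0.2 or more, the shares were 17.1% and 6.96%. For GF and SPF libraries of the same tissue the gaps were smaller, with 4.07% within and 4.03% between states in brain (exact permutation p = 0.4) and 3.06% and 2.71% in cecum (exact permutation p = 0.1). The cecum split, and the brain split at 0.2 or more (22.0% and 20.4%), were the most extreme of their 10 splits, while the cecum split at 0.2 or more (13.99% and 12.81%) was not (exact permutation p = 0.2). The most extreme split gives the smallest p that 3 libraries against 3 allow, so a separation by state is left open. These comparisons of sharing, and the count of sites listed in 1 tissue alone, were chosen after the data were examined.

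In all 6 brain libraries and no cecum library, 35 sites were listed, and 5 sites showed the opposite. Leaving out a library relaxes this rule too, so these counts can only stay or rise. The brain count was 68 without brain SPF replicate 3, the shortest list, and the cecum count was 10 without cecum SPF replicate 2. The brain sites included positions 109533929 of chromosome 12 (0.624), 41518020 of chromosome 4 (0.533), 115969783 of chromosome 11 (0.469) and 75224007 of chromosome 1, at 0.420 ± 0.0748 (SD, n = 6). Several lay near each other, such as positions 69234325, 69245215 and 69251112 of chromosome 11, at 0.188, 0.293 and 0.245, and positions 135102312 and 135102380 of chromosome X, at 0.160 and 0.116. The cecum sites were positions 27630368 of chromosome 8 (0.383), 135041263 of chromosome 5 (0.357), 57864050 of chromosome 19 (0.217), 37140274 of chromosome 9 (0.176) and 156623301 of chromosome 2 (0.153). Counted in 10 kb regions, 47 had a site in every brain library and no cecum library and 34 the opposite. The region of chromosome 6 from 30770001 to 30780000 held 4.5 ± 0.837 sites per brain library, and the region of chromosome 3 from 108720001 to 108730000 held 4.17 ± 2.40 sites per cecum library (SD, n = 6 each).

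Among the 41 sites listed in at least 4 libraries of each tissue, 4 differed in level (limma with the GF or SPF state as a covariate, Benjamini-Hochberg adjusted p under 0.05). Higher in brain were position 71821817 of chromosome 8, at 0.420 ± 0.0180 in brain (n = 5) and 0.141 ± 0.0225 in cecum (n = 6; limma adjusted p = 1.73e-07), position 111883125 of chromosome 8, at 0.444 ± 0.0748 (n = 6) and 0.168 ± 0.0211 (n = 5; limma adjusted p = 5.15e-06), and position 42059763 of chromosome 10, at 0.298 ± 0.0459 and 0.160 ± 0.0455 (n = 5 each; limma adjusted p = 0.00553). Higher in cecum was position 131365133 of chromosome 6, at 0.137 ± 0.0308 in brain (n = 4) and 0.247 ± 0.0463 in cecum (n = 5; limma adjusted p = 0.00611). At each of the 4 sites the levels of the listed brain and cecum libraries did not overlap. The count of 4 depended on the settings, with 3 to 5 sites without single libraries. When all 12 libraries had to list a site, none of these 4 could be tested, and 1 other site of the 9 left passed. The call at position 131365133 was lost in an alternative given in the closing section. The numbers of listed sites, 6043 ± 2237 in brain and 5322 ± 1487 in cecum (SD, n = 6 each), did not differ beyond their spread (exact permutation p = 0.509, two-sided), and their order was opposite in GF and SPF mice, at 1944 and -501. The mean level over the 9 sites listed in all 12 libraries was 0.316 ± 0.0230 in brain and 0.304 ± 0.0105 in cecum (SD, n = 6 each; exact permutation p = 0.266, two-sided, adjusted p = 0.399). Without brain SPF replicate 3 the difference was 0.0312 over 14 sites (exact p = 0.0303, adjusted p = 0.182), and without cecum GF replicate 1 it was 0.0379 over 10 sites (exact p = 0.0173, adjusted p = 0.104), so neither passed after adjustment. In both cases the sites averaged also changed. Position 71821817 of chromosome 8 was among those that entered in the first case. Position 111883125 was the only site that entered in the second. Both were higher in brain, as given above, so these differences do not reflect the library left out alone.

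**Figure D3:**
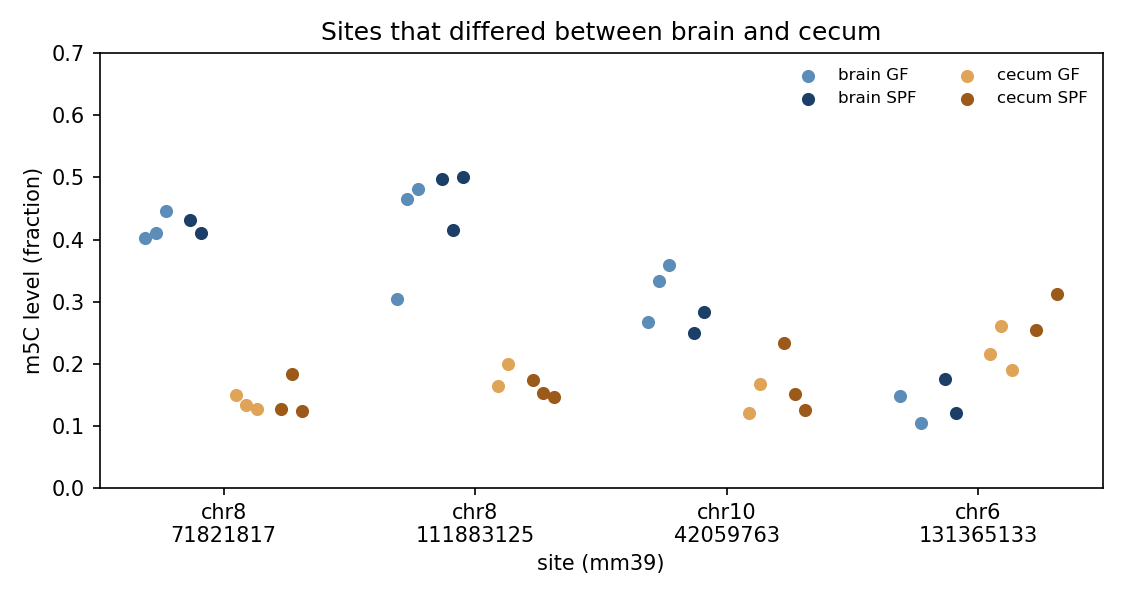
m5C level as a fraction at the 4 sites that differed between brain and cecum, with 1 point for each library that listed the site, coloured by tissue and state. At position 71821817 of chromosome 8 the brain libraries lie between 0.403 and 0.446 and the cecum libraries between 0.125 and 0.183.

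Whether the GF and SPF difference at a site depended on the tissue was tested at 29 sites listed in at least 2 libraries of each group. None had an adjusted p under 0.05 (limma interaction term), 0 of 29 passed, and 1 had an unadjusted p under 0.05. That site, position 85397525 of chromosome 8, stood at 0.414 in GF brain and 0.292 in SPF brain, and at 0.338 in GF cecum and 0.399 in SPF cecum (limma adjusted p = 0.494). The next smallest p belonged to position 40154408 of chromosome 17, at 0.250 and 0.285 in brain and 0.275 and 0.206 in cecum.

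In HCT116, the library with the NSUN2 plasmid listed 8460 sites (exact Poisson 95% interval 8281 to 8642, for counting error only) and the library with the empty plasmid 7401 (7233 to 7572), a ratio of 1.14. Sites at 0.2 or more numbered 422 with NSUN2 and 304 with the empty plasmid, a ratio of 1.39 (exact 95% interval 1.20 to 1.61). They made up 4.99% of the NSUN2 list (exact binomial 95% interval 4.53 to 5.47) and 4.11% of the empty-plasmid list (3.67 to 4.58). At 0.5 or more the order was opposite, with 22 sites with NSUN2 and 39 with the empty plasmid. Part of this gap came from pairs of sites with 1 common spacing, described in the closing section. Without them the counts were 20 with NSUN2 and 27 with the empty plasmid. With 1 library per plasmid these differences have no replicate check, and without read numbers no site could be tested.

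The 389 HCT116 sites listed in both libraries shifted little as a whole. The median difference of NSUN2 from empty plasmid was 0.002, with quartiles of -0.029 and 0.031, and 196 sites were higher and 180 lower with NSUN2. Among the sites that differed by at least 0.1, 27 were higher with NSUN2 and 13 lower. Sites that differed by that much made up 9.30% to 15.5% of the shared sites in pairs of mouse libraries of the same group. The largest increases were at position 144467296 of chromosome 8 (0.545 with the empty plasmid, 0.818 with NSUN2), position 79086571 of chromosome 17 (0.107 and 0.36), position 156547900 of chromosome 6 (0.615 and 0.864), position 1391947 of chromosome X (0.141 and 0.388), position 129556184 of chromosome 3 (0.111 and 0.351) and position 50551110 of chromosome 17 (0.26 and 0.5). Positions 134927703 and 134926742 of chromosome 5 lay close together, at 0.514 and 0.25 with the empty plasmid and 0.671 and 0.4 with NSUN2. The largest decreases were at position 1439568 of chromosome 1 (0.393 and 0.118), position 81109916 of chromosome 17 (0.333 and 0.147) and position 22371657 of chromosome 15 (0.537 and 0.368). The highest shared sites included position 91387307 of chromosome 1 (0.99 and 1.0), position 14085053 of chromosome 21 (0.897 and 0.963) and position 127506470 of chromosome 9 (0.764 and 0.832).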

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

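The tests of medians, of low levels, of neighbouring sites and of bisulfite conversion, the use of a planned leave-out to test the lowest brain library, the site sharing and one-tissue counts, and the shuffling of states within tissue were chosen after the results were seen. One site was listed in opposite states in the 2 tissues. Position 69812065 of chromosome 11 was listed in all GF and no SPF brain libraries, at 0.119 ± 0.0142, and in all SPF and no GF cecum libraries, at 0.126 ± 0.0170 (SD, n = 3 each). The difference between the tissues was not tested, and both levels lie close to the limit of 0.1.

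The mean level over shared sites was lower in GF than in SPF in brain and in cecum, by -0.0265 on average, while library medians over the same sites differed by -0.0158 (permutation within tissue, p = 0.285) and the median difference at single sites was -0.0268 in brain and -0.0122 in cecum. With the number of listed sites as a covariate, with 1 slope for both tissues, the difference was -0.0270 (permutation within tissue, 400 arrangements, p = 0.025). That number differed between GF and SPF by 691 in brain and by -1754 in cecum. With opposite signs, 1 common slope could hardly remove a shift seen in both tissues. An effect of the number that differs between tissues is left open, and the p rests on states already seen to separate. Whether the brain part rests on brain GF replicate 1, the lowest library, cannot be told apart from a shift of the group: without it the brain difference was -0.0111 (exact permutation p = 0.3), and the average of -0.0182 decides nothing, since its cecum part cannot move. Incomplete bisulfite conversion in SPF libraries, which would move low levels most, may still contribute. The sites of higher level moved further by -0.0241 ± 0.0134 in brain and -0.00910 ± 0.0208 in cecum (difference ± SE over sites). This SE leaves out the spread between libraries. The values are too close to 0 to decide, and levels under 0.1 are missing. An effect of the microbiota, a difference between the mouse colonies and differences in coverage stay open.

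Most positions, 95.8%, were listed in 1 mouse library only. Sampling noise near the lower limit may account for much of this, since 93.9% of sites at 0.4 or more recurred in the tissue against 8.42% just above the limit. Transcripts covered in 1 library only cannot be told apart from that without read numbers. Of the positions listed in 1 library of a tissue, 12.9% on average had a site of another library of that tissue within 25 nt, against 1.19% after positions were moved by 1 kb. No biological explanation was tested.

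In all 6 libraries of one tissue and none of the other, 40 sites were listed. Chance can be excluded for this count, which 1 of 462 splits of the libraries, the real one, reached, the highest of the others giving 2. Whether the transcripts were present in the other tissue cannot be told apart from a difference in methylation, since coverage is missing. Only 7.5% of these sites lay in a 10 kb region where at least 4 libraries of the other tissue listed a site. For 23 of the 40, at least 1 library of the other tissue listed a site in the region, and for 17 none did. The share with at least 4 was 18.2% in the 44 cases where the other tissue did list the site itself (Fisher's exact p = 0.201). Sites listed in every mouse library enter these cases once per tissue, so the cases are not independent. This comparison was added after the 7.5% was seen, when the prediction written before it would have favoured missing transcripts. A tissue difference in expression or in methylation stays open.

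For the 4 sites that differed between brain and cecum, 2 of 100 splits, the real one included, gave as many. The other splits were a random sample of those possible, and the highest of them also gave 4. Chance is therefore unlikely at the 0.05 level but not excluded. For the interaction the real count was 0, which 100 of 100 splits must reach (highest other 2), so the splits say nothing about chance. For GF against SPF the 10 splits of 6 libraries are too few for such a statement, and 10 of 10 must reach the real count of 0 changed sites in brain (highest other 2) and in cecum (highest other 0). The counts of sites listed in one group alone were 15 in brain (highest other 42, 7 splits as large) and 28 in cecum (highest other 20, 1 split as large).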

How the results depend on the processing

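Of 206 alternative values of the main results, 171 kept their direction and their side of the threshold or their size, as did 263 of 268 values of single sites. Some of these could not change. An exact permutation test of 3 libraries against 3 cannot give a p under 0.1, so it could not pass the threshold. Without mitochondrial and unplaced sequences, the single-site tests and the means over shared sites used the same sites and gave the same values. These counts are therefore no measure of how firm the results are. Alternatives chosen after the data were seen are the offset, untransformed levels, medians over shared sites, 10 kb regions, all settings of site sharing, of one-tissue listing and of the test within tissue. With levels only, coverage minimums, stricter significance, pooled levels, edgeR, models of reads, Fisher's test on reads, removal of ribosomal and transfer RNA genes, sequence types, transcript positions and gene lists were not run. Except where a setting itself changes the rule or the sites compared, the cause of the changes below was not tested.

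Numbers of listed sites: the brain difference was -11.7 at 0.2 or more, and ran from -959 to 2296 without single libraries. The cecum difference ran from -2520 to -984 and that of brain from cecum from 149 to 1451. Mean levels: over each library's own sites the GF and SPF difference was -0.00136 in brain and 3.81e-05 in cecum. Without single libraries, which can also change the sites averaged, brain against cecum ran from 0.00650 to 0.0379 and the test within tissue from -0.0304 to -0.0182. The latter no longer passed with medians, at -0.0158, or with each library's own sites, at -0.000663. Brain site sharing of GF and SPF was -0.113 in 10 kb regions.

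Changed sites without single libraries numbered 0 to 1 in brain (position 152387987 of chromosome 4 without SPF replicate 1, limma adjusted p = 0.000225), 0 to 1 in cecum (position 4408254 of chromosome 16 without GF replicate 3, limma adjusted p = 0.0243) and 3 to 5 between brain and cecum. When sites had to be listed in all 12 libraries, brain against cecum gave 1 of 9 sites. The 4 sites of the main test were not among those 9. Sites listed in one group alone were 2 in brain and 2 in cecum at 0.2 or more, 355 and 364 with 2 of 3 libraries required, and 161 and 210 in 10 kb regions. They were 32 to 115 and 74 to 131 without single libraries, which relaxes the rule, so that these counts can only stay or rise. Sites listed in one tissue alone were 14 at 0.2 or more, 196 with 4 of 6 libraries required, 81 in 10 kb regions, and 41 to 73 without single libraries, where the rule is relaxed in the same way. The HCT116 ratio was 1.39 at 0.2 or more and the median shift there 0.012.

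Neither the labels nor the levels showed that the replicate numbers pair the libraries. Same-numbered GF and SPF libraries correlated in their deviations at -8.73e-05, 0.215 and -0.0154 in brain and 0.0983, 0.116 and 0.263 in cecum, and same-numbered brain and cecum libraries at 0.329, -0.0396 and 0.481 in GF and -0.169, -0.295 and -0.288 in SPF, and not every library correlated best with its own number. With the replicate number as a block, changed sites numbered 2 in brain, 0 in cecum and 3 between tissues. Under the block, position 152387987 of chromosome 4 (limma adjusted p = 3.05e-06) and position 69670443 of chromosome 11 (limma adjusted p = 0.0431) passed in brain, and position 131365133 of chromosome 6 no longer passed between tissues (limma adjusted p = 0.113). At position 152387987 the same-numbered GF and SPF levels were 0.212 and 0.228, 0.226 and 0.571, and 0.125 and 0.647. These gaps were far from alike. In limma the spread of a site is drawn toward that of all sites, so the small p does not measure the spread at this site alone.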

Other observations

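A mean level of at least 0.8 in at least 3 libraries was seen at 11 mouse positions, 8 of them in both tissues. These positions were chosen after their values were seen. Without conversion rates, read numbers or annotation, methylation there cannot be told apart from cytosines left unconverted or read as unconverted for another reason. Besides the positions on chromosomes 9 and 12 given above, position 5925524 of chromosome 3 stood at 0.983 ± 0.00501 in 10 libraries, position 46115252 of chromosome 1 at 0.986 ± 0.0266 in 8, position 7209347 of chromosome 17 at 0.990 ± 0.0160 in 6 and position 54832328 of chromosome 18 at 0.983 ± 0.0241 in 5 (SD over the listing libraries). Position 27711711 of chromosome 16 was listed at 1.0 in 4 cecum libraries, 3 of them SPF, and in no brain library. On the mitochondrial chromosome, position 911 stood at 0.863 ± 0.0214 in 3 libraries of both tissues and position 13722 at 0.280 in 6.

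HCT116 sites at 0.8 or more that were listed with the empty plasmid alone fell largely into pairs (10 of 13), which were examined after their values were seen. In 6 pairs, on chromosome 21, a patch sequence of it, an unlocalised sequence of chromosome 22 and an unplaced sequence, the sites lay exactly 665 nt apart, for example at positions 8400692 and 8401357 of chromosome 21, at 0.989 and 0.971 with the empty plasmid. All 12 paired sites were listed with the empty plasmid, at 0.837 to 0.994, and 2 with NSUN2. A hypothesis is that these are copies of 1 repeated locus that share reads, which the single spacing of all 6 pairs goes with, and that the number listed may depend on how reads were placed or on how much of that RNA each library held. Ribosomal RNA genes are known to be repeated on these chromosomes and to carry m5C in their transcripts, and whether the pairs lie in them was not analysed here. Without the pairs, sites at 0.5 or more numbered 27 with the empty plasmid and 20 with NSUN2.

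The HCT116 lists also had more entries at the limit itself. Of their sites, 25.1% with the empty plasmid and 25.2% with NSUN2 were listed at exactly 0.1, against 6.76% to 8.31% in the mouse libraries.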
